A study of Mus musculus with 8 samples.

How the data were processed

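PrL tissue in 4 Sham and 4 SNI samples (C57 mice) was profiled by bulk RNA sequencing. Per the labels' protocols, total RNA was extracted with TRIzol, poly(A) RNA was selected and fragmented, and libraries were made with dUTP in the second strand, which was removed before amplification. That chemistry keeps the strand of the transcript. Whether the counting used it is not given in the sources used here. Genes that overlap, lie antisense to each other or have near-identical copies are therefore called uncertain.

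The deposited table holds whole-number counts of reads per gene, keyed by gene symbol. Per the submitters' processing notes, reads were handled with fastp, HISAT2 and StringTie on GRCm38, with no versions given. How assembled output became counts, and which annotation and filter were used, is not given in the sources used here. The smallest count is 1, so the table holds genes counted at least 1 time in every library, and a gene with no count in any library has no row. Tnf and Xist have 0 rows, for a reason not given in the sources used here. Of 14765 symbols, 14661 matched GENCODE M21 (GRCm38), 14636 of them protein coding, and 104 did not match. Coordinates come from that annotation.

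Library totals were 14735602 to 19602487 counts, which limits precision for genes near 1 CPM, where a library holds about 15 to 20 reads. Spearman correlations over genes were 0.991 to 0.995 within sham, 0.989 to 0.993 within SNI and 0.982 to 0.992 between groups. No library was a copy of another: the chi-square per degree of freedom between counts of same-group pairs was 7.77 to 29.7, far above sampling noise.

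Differential expression used edgeR 4.0.16 in R 4.3.3 on the deposited counts. Genes were kept by filterByExpr (13911 of 14765), scaled by TMM and tested with the quasi-likelihood F-test (robust, two-sided, group as the only term), with Benjamini-Hochberg adjustment and an FDR threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of the F statistic. CPM values are TMM-scaled. The biological coefficient of variation was 12.1%.

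Before the data were examined, 45 gene lists of cell types and pathways were fixed for testing with camera (limma 3.58.1, preset correlation 0.01), on the same fit. Lists with at least 5 tested members entered. camera with an estimated correlation, camera on ranks and fry stood beside it. A list value per library is the mean over members of log2 CPM (prior count 2) minus each gene's mean, compared by an exact two-sided permutation test over the 70 assignments of 8 libraries. A list of sex-linked genes served only as a check of the animals. The genes named are the 15 largest rises and 15 largest falls among genes at FDR 0.05 with 4 SNI values all above or below the 4 sham values and a mean log2 CPM of at least 0. Predicted genes and pseudogenes were named only among the 5 largest. The 3 members of smallest p in each described list were added, as were Tnf, Tnfrsf1a and Gria1, which the naming rule took up whatever their values. Some genes that the rule takes are not reported here.

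The method was tested on simulated counts for this comparison with 13831 genes. It recovered 41.2% of 68 genes changed by 0.5 on the log2 scale, 81.5% of 65 changed by 1 and 97% of 66 changed by 2, with 7 of 152 calls false. Simulated groups with no change gave 0 calls of genes and 0 of lists. A simulation with changed genes and a shifted list (13812 genes, 45 lists) called that list and 0 others. These simulated genes were independent, so the list result does not cover correlated genes.

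Alternatives were other scalings (RLE, upper quartile, library totals), no low-count filter, a filter of 1 CPM in 4 libraries, DESeq2 1.42.0, limma voom with quality weights, a replicate block, each library left out in turn, and other thresholds. Added after seeing the data were offsets correcting for GC content, a striatal marker covariate, and leaving out SNI replicates 2 and 4, or 2 and 3.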

Results

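Gene expression was measured by bulk poly(A) RNA sequencing of PrL tissue (taken here as the prelimbic part of the mouse medial prefrontal cortex, from the series' topic) in 2 groups of C57 mice. SNI, which in pain research stands for spared nerve injury, a surgical model of lasting neuropathic pain, was compared with sham, the control group. There were 4 Sham and 4 SNI libraries. Each library held between 14735602 and 19602487 counts over 14765 genes, with a median count per gene of 343 to 466. Sham replicates 1 to 4 held 14957654, 15265051, 16220279 and 17694715 counts, and SNI replicates 1 to 4 held 15850026, 19602487, 14735602 and 16630970. The labels do not say whether each library came from a separate mouse, so the p-values measure the spread between these libraries, which may be technical in part. The comparison asks how the PrL transcriptome differs between mice with the nerve injury and controls, in a study of how cortex controls pain and anxiety-like behaviour.

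The gene that fell most was Cx3cr1, the fractalkine receptor that in the brain is carried mainly by microglia. Its level was 51.2 ± 4.47 CPM in sham and 1.93 ± 0.317 CPM in SNI (SD, n = 4 libraries each), a log2 fold change of -4.74 ± 0.133 (SE), or 26.8-fold. The raw counts were 661, 780, 875 and 921 in the sham libraries and 36, 31, 32 and 30 in the SNI libraries. Cx3cl1, the neuronal ligand of this receptor, also fell, from 881 ± 33.8 to 574 ± 80.0 CPM (SD, n = 4 libraries each, log2 fold change -0.62). The gene that rose most was Dnah6, an axonemal dynein heavy chain, from 0.460 ± 0.0987 to 7.87 ± 2.27 CPM (SD, n = 4 libraries each, 16.9-fold). The edgeR adjusted p was 2.41e-12 for Cx3cr1, 0.00259 for Cx3cl1 and 1.29e-06 for Dnah6. In GRCm38, Cx3cr1 lies on chromosome 9 from 119901616 to 120069879, and Dnah6 on chromosome 6 from 73017606 to 73221651. The annotated span of Cx3cr1 contains other genes, among them Csrnp1, Gorasp1 and Wdr48, whose log2 fold changes were -0.04, -0.15 and -0.05.

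Over all genes, 698 of the 13911 tested differed at an FDR of 0.05, 299 higher and 399 lower in SNI. Most changes were small: the median size among the 698 was 0.50 on the log2 scale, and 99 changed by at least 1 (61 higher, 38 lower). In 638 of the 698 the 4 SNI values all lay above or all below the 4 sham values. That separation held for 12.7% of all tested genes, against 2.86% by chance. The first principal component held 35.2% of the variance and separated the groups, with sham libraries from -23.5 to -11.2 and SNI libraries from 7.19 to 30.4. Scaling by library totals alone gave 446 higher and 276 lower genes. The count of 698 became 447, 430 and 258 without Sham replicates 1, 2 and 3, 297 without SNI replicate 3, 438 without SNI replicates 2 and 4, 178 without SNI replicates 2 and 3 (both pairs chosen after seeing the data), and 1153 with DESeq2. It became 7 with a per-library striatal marker value as a covariate, whose values were higher on average in SNI but overlapped between the groups.

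Among the other large rises, Lgals3, which encodes galectin-3, a lectin of activated phagocytes, had a log2 fold change of 2.88 ± 0.568 (SE). Ttr, the thyroxine carrier made in choroid plexus, had 2.46. Ccl17, a chemokine, had 1.86, and C1s1, a complement protease, had 2.08, or 1.41 without SNI replicate 3. Ido1, a tryptophan-degrading enzyme, had 1.99, Fmo2, a monooxygenase, 1.94, and Cfap126, a cilium gene, 1.80. The remaining rises by the naming rule were Zfp992 (2.43), Hbq1a (2.27), Ano2 (2.14), Serpina9 (2.13), Fbxw15 (1.93) and Ankub1 (1.88). Most of these genes were scarce: apart from Hba-a1, Dnah6 and Serpina9, their SNI means lay below 4 CPM.

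Among the large falls, Cort, the neuropeptide cortistatin of cortical interneurons, went from 13.5 ± 2.44 to 3.94 ± 1.32 CPM (SD, n = 4 libraries each), a log2 fold change of -1.76 ± 0.210 (SE). Colq, the collagen tail of acetylcholinesterase, had a log2 fold change of -2.10, Neurog2, a neurogenic transcription factor, -1.91, and Sod3, the extracellular superoxide dismutase, -1.53. Irf7, Ifi27l2a, Irgm2 and Tgtp2, all genes induced by interferons, had -1.69, -1.63, -1.77 and -1.58. Wif1, a Wnt inhibitor, had -1.37. Olfr464 (-2.14), Trim72 (-1.59), Spink10 (-1.58) and Tspan11 (-1.36) completed the list.

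The 2 alpha-globin copies moved in opposite directions: Hba-a1 rose from 15.98 ± 5.23 to 81.5 ± 32.6 CPM, and Hba-a2 fell from 3.31 ± 1.53 to 0.257 ± 0.203 CPM (SD, n = 4 libraries each). The copies are near-identical, so how reads were divided between them is uncertain. Their sum was 19.3 ± 6.74 CPM in sham and 81.7 ± 32.5 CPM in SNI (exact two-sided permutation p = 0.0286, the smallest that 4 against 4 allows). Irgm2 overlaps Igtp on the same strand, and Tgtp2 has the close copy Tgtp1. Hbq1a, Zfp992, Fbxw15, C1s1 and Olfr464 have close relatives or overlapping genes. The values of all these genes are uncertain too. The same holds for genes whose span overlaps another annotated gene: Cx3cr1, Dnah6, Serpina9, Colq, Ano2, Irf7 (with Phrf1 on the opposite strand), Spink10 (with Spink13 and Spink7), Trim72 and Tspan11.

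**Figure D1:**
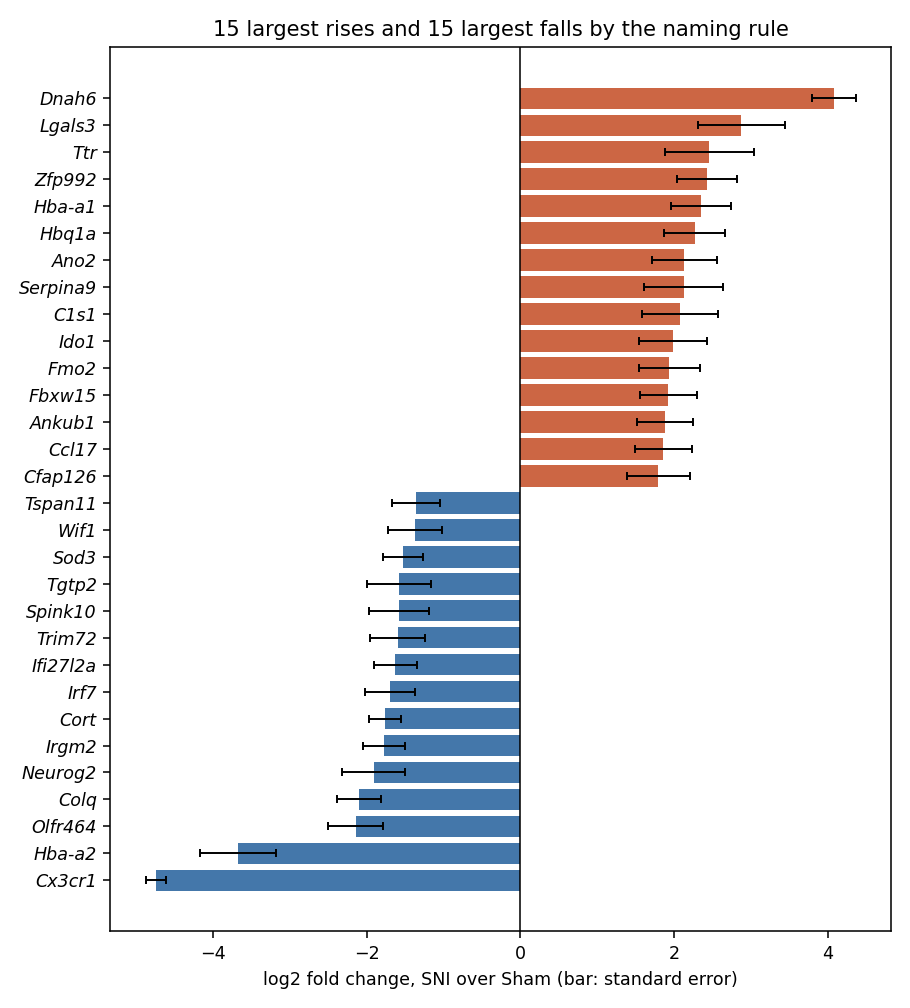
Log2 fold change of SNI over Sham (horizontal axis; bars show the edgeR estimate, whiskers the standard error) for the 15 largest rises and 15 largest falls chosen by the fixed naming rule. Cx3cr1 at -4.74 and Dnah6 at 4.08 lie at the ends.

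Of these 30 genes, 16 passed the threshold whichever single library was left out. Cx3cr1, Dnah6, Cort and Colq were the 4 that passed in each of the 20 alternatives. C1s1, Cfap126, Hba-a1, Ido1, Irf7, Lgals3, Neurog2, Serpina9, Spink10, Tgtp2, Trim72, Tspan11, Ttr and Wif1 each lost the call without at least 1 library. Their highest edgeR adjusted p ran from 0.0523 (Trim72 without SNI replicate 2) to 0.137 (Tgtp2 without Sham replicate 3). Leaving out 1 library moved 4 of the 30 by more than 1.5-fold. Without SNI replicate 3 the log2 fold changes of Lgals3 and C1s1 were 2.22 and 1.41, without Sham replicate 4 that of Ttr was 3.05, and without SNI replicate 1 that of Hba-a2 was -4.35.

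Gene groups are described next by lists fixed before the data were examined. Of 45 lists tested with camera at a preset inter-gene correlation of 0.01, 20 passed, 11 higher and 9 lower in SNI. With a correlation estimated from the data, 0 passed, 6 had an unadjusted p under 0.05, and the adjusted p of the 20 ran from 0.2 to 0.68. fry, which tests whether a list's own members move in 1 direction on balance, called 6. Its mixed form, which tests whether members change in either direction, called 35 of the 45. Lists said below not to have passed are judged by camera, and some of them passed this mixed form. The exact test on list values per library gave 9 lists at an unadjusted p under 0.05 and 0 after adjustment. The calls of 4 lists ended when a library was left out: thalamic and septal markers without Sham replicate 1 or SNI replicate 2 (adjusted p = 0.0725 and 0.0868), oligodendrocyte genes without Sham replicates 2 or 3 or SNI replicate 4 (0.352, 0.0818 and 0.158), neurotrophins without Sham replicate 3 (0.0692), and peripheral immune markers without SNI replicate 3 (0.0799). The counts of members below therefore rest on the gene-level test. They are given over all genes tested and, for most lists, then adjusted over the list alone.

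Several markers of upper cortical layers fell and some deep-layer markers rose in SNI. Of 12 upper-layer markers 3 fell and 0 rose, also 3 adjusted over the list alone: Lamp5 from 215 ± 35.3 to 123 ± 10.9 CPM, Mdga1 from 21.8 ± 6.51 to 12.2 ± 1.83 CPM, and Cux2 from 80.6 ± 7.91 to 61.1 ± 8.03 CPM (SD, n = 4 libraries each). The list's camera adjusted p was 0.00034, and 0.22 with an estimated correlation. Of 17 deep-layer markers 2 rose, 3 adjusted over the list alone. These were Hs3st4, from 67.4 ± 9.11 to 97.0 ± 6.42 CPM, and Ntsr1, from 11.6 ± 2.18 to 17.3 ± 1.41 CPM (SD, n = 4 libraries each). Foxp2 had a log2 fold change of 0.95 with an edgeR adjusted p of 0.0746. This list's camera adjusted p was 0.0054, and 0.43 with an estimated correlation. Its value in Sham replicate 1, 0.165, lay above those of all SNI libraries (0.102 to 0.145). Of 12 general excitatory neuron markers 3 fell, 5 adjusted over the list alone: Nrn1 (log2 fold change -0.79), Mef2c (-0.40) and Itpka (-0.44). Their adjusted p was 7.6e-05 by camera and 0.43 with an estimated correlation. Of 20 GABAergic neuron markers 1 fell, Cck (-0.43), 2 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.1). Kcnc1 and Erbb4 had -0.30 and 0.20 and did not pass. The calls of Mdga1, Cux2, Ntsr1, Mef2c and Itpka ended without at least 1 library. Their highest edgeR adjusted p was 0.0623 for Mdga1 (without SNI replicate 2). Without Sham replicate 3 it was 0.101 for Cux2 and Itpka, 0.0766 for Ntsr1 and 0.0588 for Mef2c. Striatal markers, described below, were highest in SNI replicates 2 and 4.

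**Figure D2:**
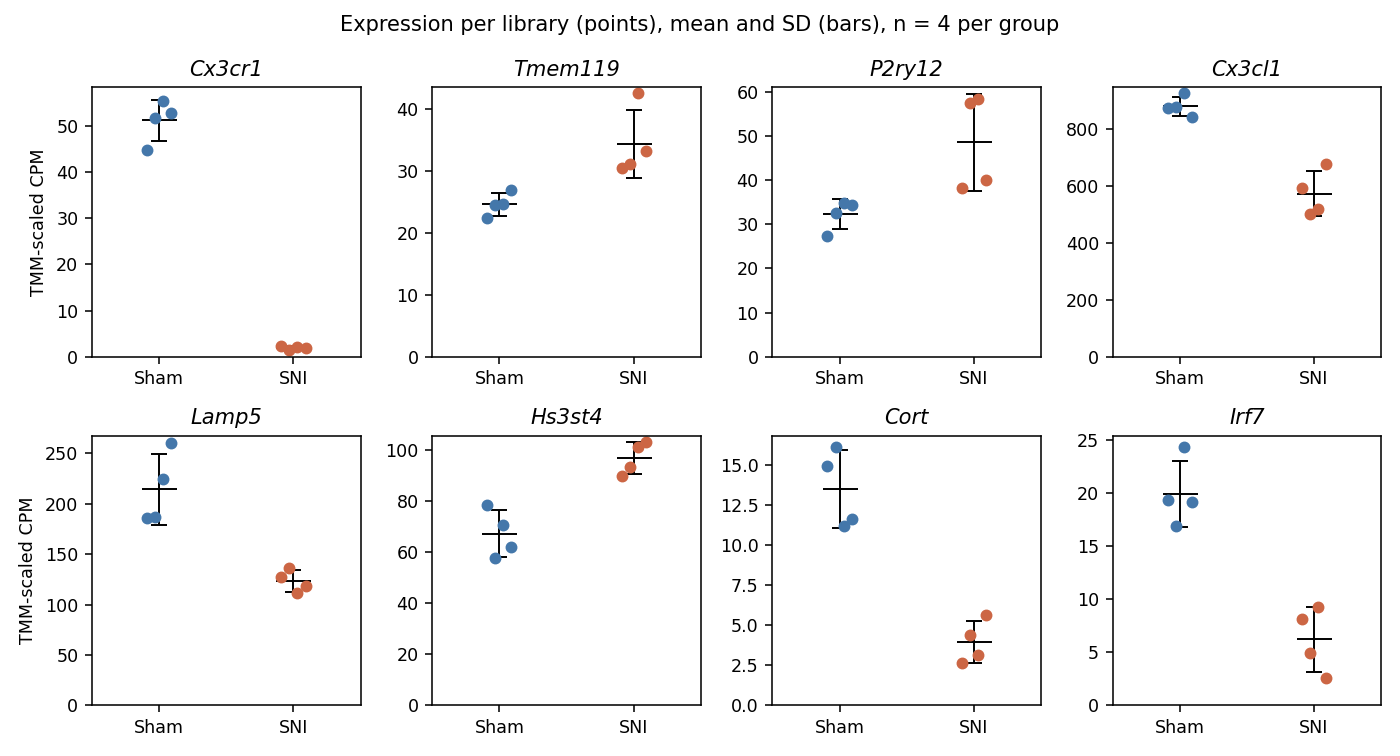
TMM-scaled CPM (vertical axis, from 0, scale differing by panel) in each library, as points, for 8 genes in Sham and SNI; black bars show the mean and SD of 4 libraries. Cx3cr1 lay between 44.8 and 55.3 in sham and between 1.54 and 2.23 in SNI, while the microglial genes Tmem119 and P2ry12 were higher in SNI.

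Several genes of the glutamatergic postsynapse fell. Of 31 NMDA receptor and postsynaptic density genes 6 fell and 0 rose, with 19 lower and 2 higher adjusted over the list alone. Shank2, a scaffold protein, had a log2 fold change of -0.49 ± 0.0931 (SE). Grin2a and Grin2b, NMDA receptor subunits, had -0.43 and -0.41. The list's camera adjusted p was 2.8e-09, and 0.31 with an estimated correlation. Of 33 AMPA and kainate receptor genes 3 fell: Cacng3 (-0.61), Olfm2 (-0.57) and Cacng2 (-0.27), which are auxiliary rather than pore-forming proteins. Adjusted over the list alone 6 fell, among them Gria4, a pore-forming subunit (-0.30). This list's camera adjusted p was 1e-04, and 0.43 with an estimated correlation. Gria1, the GluA1 subunit, had 346 ± 28.3 CPM in sham and 316 ± 34.3 CPM in SNI (SD, n = 4 libraries each) and did not pass (log2 fold change -0.13, edgeR adjusted p = 0.433). Of 20 metabotropic glutamate receptor and transport genes 1 fell, also 1 adjusted over the list alone. It was Grm2, a presynaptic receptor, which went from 97.2 ± 7.04 to 55.0 ± 12.8 CPM (SD, n = 4 libraries each). Grm7 and Slc38a2 had -0.28 and 0.22 and did not pass. The call of Grin2b ended without Sham replicate 3 (edgeR adjusted p = 0.0848), SNI replicate 3 or SNI replicate 4. That of Cacng2 ended without 7 of the 8 libraries in turn (highest 0.159). In SNI the list values were lowest in replicates 2 and 3: -0.248 and -0.101 for the NMDA list against -0.0534 and -0.0412 in replicates 1 and 4, and -0.166 and -0.134 for the AMPA list against 0.00535 and -0.00484. The same replicates had the lowest values of excitatory neuron markers (-0.277 and -0.243) and the highest SNI values of astrocyte markers (0.103 and 0.275).

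Several ion channel and vesicle release genes also fell. Of 57 potassium channel genes 9 fell and 1 rose, with 17 lower and 1 higher adjusted over the list alone. Kcnv1, Kcnb2 and Kcnh5 had log2 fold changes of -0.61, -0.47 and -1.01. For this list the camera adjusted p was 3.2e-06, and 0.31 with an estimated correlation. Of 29 sodium, calcium and HCN channel genes 3 fell, 10 adjusted over the list alone, and the 3 were calcium channels: Cacna1i (-0.77), Cacna1a (-0.44) and Cacna1b (-0.30). Here the camera adjusted p was 0.00016, and 0.31 with an estimated correlation. Of 33 synaptic vesicle release genes 4 fell, with 5 lower and 1 higher adjusted over the list alone, led by Unc13a, a vesicle priming factor (-0.51), and the syntaxin Stx1a (-0.45). The list's adjusted p by camera was 6.6e-06, and 0.43 with an estimated correlation. Of 26 GABA receptor and handling genes 1 rose, Gabra2 (0.83 ± 0.142 SE), and 1 fell, Slc12a5, the chloride extruder KCC2 (-0.36), with 2 higher and 4 lower adjusted over the list alone. Gabrg1 had 0.40 and did not pass, nor did this list (camera adjusted p = 0.1). The calls of Cacna1b and Slc12a5 ended without 7 of the 8 libraries in turn, with highest edgeR adjusted p of 0.148 and 0.11. That of Stx1a ended without Sham replicate 3 (0.0625) and without SNI replicate 3. SNI replicates 2 and 3 stood apart here too. Their list values were -0.122 and -0.145 for sodium, calcium and HCN channels and -0.201 and -0.142 for vesicle release, while replicates 1 and 4 lay between 0.00383 and 0.0173 on both lists.

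Several neuropeptide, plasticity and receptor genes fell. Of 41 neuropeptide and receptor genes 7 fell and 1 rose, the same counts adjusted over the list alone, and the list did not pass (camera adjusted p = 0.11). Besides Cort, Adcyap1, which encodes PACAP, fell by 0.75 on the log2 scale and Crhr1, a receptor of corticotropin-releasing hormone, by 0.72. Of 22 neurotrophin and plasticity genes 6 fell, with 7 lower and 2 higher adjusted over the list alone: Nptx2, a neuronal pentraxin, from 88.3 ± 8.92 to 52.2 ± 9.73 CPM (SD, n = 4 libraries each), Nrgn (-0.59), and Vgf (-0.72) among them. As a list its camera adjusted p was 0.017, and 0.43 with an estimated correlation, and SNI replicate 4 (0.0788) lay above the other SNI libraries (-0.114 to -0.039) and 3 sham libraries. Of 35 monoamine and acetylcholine receptor genes 3 fell, 4 adjusted over the list alone: Htr2a, a serotonin receptor (-0.65), Adra1b, a noradrenaline receptor (-0.77), and Chrm3, a muscarinic receptor (-0.46). That list did not pass (camera adjusted p = 0.38), and neither did 16 opioid and endocannabinoid genes (0.2), of which 0 changed. Their 3 members of smallest p, Faah, Dagla and Pdyn, had -0.32, -0.33 and 0.30. Of 27 perineuronal net and matrix genes 5 fell, with 6 lower and 4 higher adjusted over the list alone, among them Hapln4 (-0.72), Ncan (-0.39) and Tnr (-0.34). By camera the adjusted p was 0.37. Of 34 immediate early genes 3 rose and 2 fell, 9 and 5 adjusted over the list alone. Sik1 (0.76) and Cyr61 (0.82) rose and Nptx2, held by this list too, fell (camera adjusted p = 0.12). The calls of Chrm3 and Tnr ended without Sham replicate 3, among others, with edgeR adjusted p of 0.119 and 0.0938.

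Interferon-stimulated genes included 10 that fell in SNI. Of 32 measured, 0 rose, and 18 fell adjusted over the list alone, and the median log2 fold change was -0.49. Ifi27 fell from 74.3 ± 6.29 to 47.9 ± 4.19 CPM, Irf9, part of the interferon-activated transcription complex, from 25.0 ± 1.45 to 15.2 ± 2.55 CPM, and Gbp3 from 18.8 ± 3.62 to 9.10 ± 2.29 CPM (SD, n = 4 libraries each). For this list the camera adjusted p was 4.6e-12, and 0.43 with an estimated correlation. The mean list value per library was 0.26 ± 0.23 in sham and -0.26 ± 0.37 in SNI (SD, n = 4 libraries each, exact two-sided permutation p = 0.0571). The lowest value, -0.75, was that of SNI replicate 4, and SNI replicate 3 (0.14) lay above Sham replicate 2 (-0.031).

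TNF signalling genes did not change at the threshold. Of 35 TNF receptor signalling components 0 passed, with 0 adjusted over the list alone, and the list's camera adjusted p was 0.35. The mixed form of fry gave this list an adjusted p of 0.013. Tnfrsf1a, the main TNF receptor, had 10.4 ± 1.84 CPM in sham and 12.4 ± 1.91 CPM in SNI (SD, n = 4 libraries each, log2 fold change 0.24, edgeR adjusted p = 0.381). Tnf had 0 rows in the table, which holds genes counted in all 8 libraries, so its level could not be compared. Ripk1, Map3k5 and Tab1 had 0.59, -0.27 and -0.28, and none passed. Of 16 NF-kB target genes 0 passed (camera adjusted p = 0.12). Its leading members Nfkbia, Csf1 and Tnfaip2 had 0.36, 0.29 and 0.76. Of 32 cytokine, chemokine and receptor genes 3 rose and 2 fell, the same counts adjusted over the list alone. They included Cx3cr1, Cx3cl1 and Ccl17 (camera adjusted p = 0.45).

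Microglial genes other than Cx3cr1 were not lower as a group. Of 18 microglia markers 2 rose, Tmem119 from 24.6 ± 1.84 to 34.4 ± 5.57 CPM and P2ry12 from 32.3 ± 3.38 to 48.6 ± 10.9 CPM (SD, n = 4 libraries each), and 1 fell, Cx3cr1. Adjusted over the list alone, 6 rose and 2 fell. The other fall was Fcrls, a microglial gene named here after its values were seen, at 31.6 ± 4.89 CPM in sham and 13.8 ± 7.10 CPM in SNI (SD, n = 4 libraries each). It had a log2 fold change of -1.19 and did not pass over all genes (edgeR adjusted p = 0.131). The list's median was 0.32 and its mean -0.03, which Cx3cr1 pulls down, and its camera adjusted p was 0.88. Of 27 reactive astrocyte genes 6 rose and 1 fell, 7 and 1 adjusted over the list alone: Serpina3n (0.89), Cd109 (2.29) and Vim (0.92) rose. The list's adjusted p by camera was 6.9e-05, and 0.43 with an estimated correlation. Of 16 general astrocyte markers 0 passed, and Fgfr3, Gfap and Acsbg1 had 0.27, 0.94 and -0.18. Of 15 complement genes 2 rose, C4b (1.68) and C1s1, with 3 higher and 1 lower adjusted over the list alone. Cd55 had -0.55 and did not pass. As a list its camera adjusted p was 0.0016, and 0.5 with an estimated correlation. Of 8 peripheral immune markers 0 passed and 1 was higher adjusted over the list alone. Ptprc, Cd4 and H2-Ab1 had 0.92, 1.35 and 1.93, the last 1.32 without SNI replicate 3 (list camera adjusted p = 0.0042, and 0.47 with an estimated correlation). SNI replicate 3 had the highest values of the reactive astrocyte, complement and peripheral immune lists (0.64, 0.82 and 1.63), and Sham replicate 4 (0.18, 0.01 and 0.23) lay above SNI replicate 4 on all 3. The calls of Tmem119, P2ry12, Vim, Cd109 and C4b ended without 4, 6, 4, 2 and 4 of the 8 libraries in turn. Their highest edgeR adjusted p were 0.0742, 0.0964, 0.0831, 0.0577 and 0.0729.

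Many ribosomal protein genes rose. Of 77 measured, 27 rose and 1 fell, with 64 higher and 1 lower adjusted over the list alone, and the median log2 fold change was 0.38. Rpl11 had 0.49, and Rpl34 was the member that fell (-0.65). These genes have many processed pseudogenes, so their single values are uncertain. In SNI the list value was 0.282 and 0.373 in replicates 2 and 3 and -0.0253 and 0.04 in replicates 1 and 4. Replicates 2 and 3 also had the lowest excitatory neuron values and the highest mitochondrial shares of counts of all 8 libraries (6.08% and 6.16%). By camera the adjusted p was 3.4e-27, and 0.43 with an estimated correlation. Of 21 antioxidant genes 3 rose, 6 adjusted over the list alone: Ftl1 (0.45), Prdx1 (0.40) and Mt2 (1.78, or 2.39 without Sham replicate 1). This list's camera adjusted p was 5.7e-05, and 0.31 with an estimated correlation. Of 23 glucocorticoid-responsive genes 4 rose and 1 fell, 8 and 1 adjusted over the list alone. Nr3c2, the mineralocorticoid receptor, rose (0.46), as did Mt2, and Cdkn1a, a cell cycle inhibitor, fell (-0.76). SNI replicate 3 stood apart with a list value of 0.494, against 0.057, -0.111 and 0.149 in SNI replicates 1, 2 and 4, and the groups overlapped (Sham replicate 4 had 0.0205). For this list the camera adjusted p was 0.0021, and 0.43 with an estimated correlation. Of 19 circadian clock genes Nr1d2 (0.45), Bhlhe41 (0.50) and Dbp (0.59) rose and Arntl (-0.46) fell, with 4 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.22). The calls of Prdx1, Mt2 and Nr3c2 ended without Sham replicate 3, with edgeR adjusted p of 0.0882, 0.118 and 0.0674.

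Some markers of neighbouring regions rose. Of 16 striatal medium spiny neuron markers 2 rose, also 2 adjusted over the list alone, and 15 had a positive fold change, with a median of 1.00. The 2 were Ido1 and Serpina9, while Drd1, a dopamine receptor, had 14.4 ± 4.50 CPM in sham and 28.3 ± 10.4 CPM in SNI (SD, n = 4 libraries each) and did not pass. The list value per library was -0.53 ± 0.59 in sham and 0.53 ± 0.61 in SNI (SD, n = 4 libraries each, exact two-sided permutation p = 0.0571), and SNI replicates 2 and 4 had the highest value, 1.05 each. The list's adjusted p by camera was 2.1e-06, and 0.43 with an estimated correlation. Of 8 choroid plexus and ependymal markers 4 rose, 7 adjusted over the list alone, led by Rarres2 (1.49), Clic6 (2.31) and Cfap126. Here the camera adjusted p was 3.2e-06, and 0.2 with an estimated correlation. Of 16 thalamic and septal markers 4 rose, also 4 adjusted over the list alone. Zic5, Prkcd and Zic4 had 0.83, 0.74 and 0.88 (camera adjusted p = 0.029, and 0.43 with an estimated correlation). Of 20 oligodendrocyte genes 0 passed, and Hapln2, Trf and Aspa had 1.03, 0.72 and 0.64 (camera adjusted p = 0.021, and 0.68 with an estimated correlation). The calls of Ido1, Serpina9, Clic6, Cfap126, Zic5, Prkcd and Zic4 ended without SNI replicate 2, among other libraries. Their highest edgeR adjusted p ran from 0.0617 (Clic6) to 0.131 (Serpina9).

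**Figure D3:**
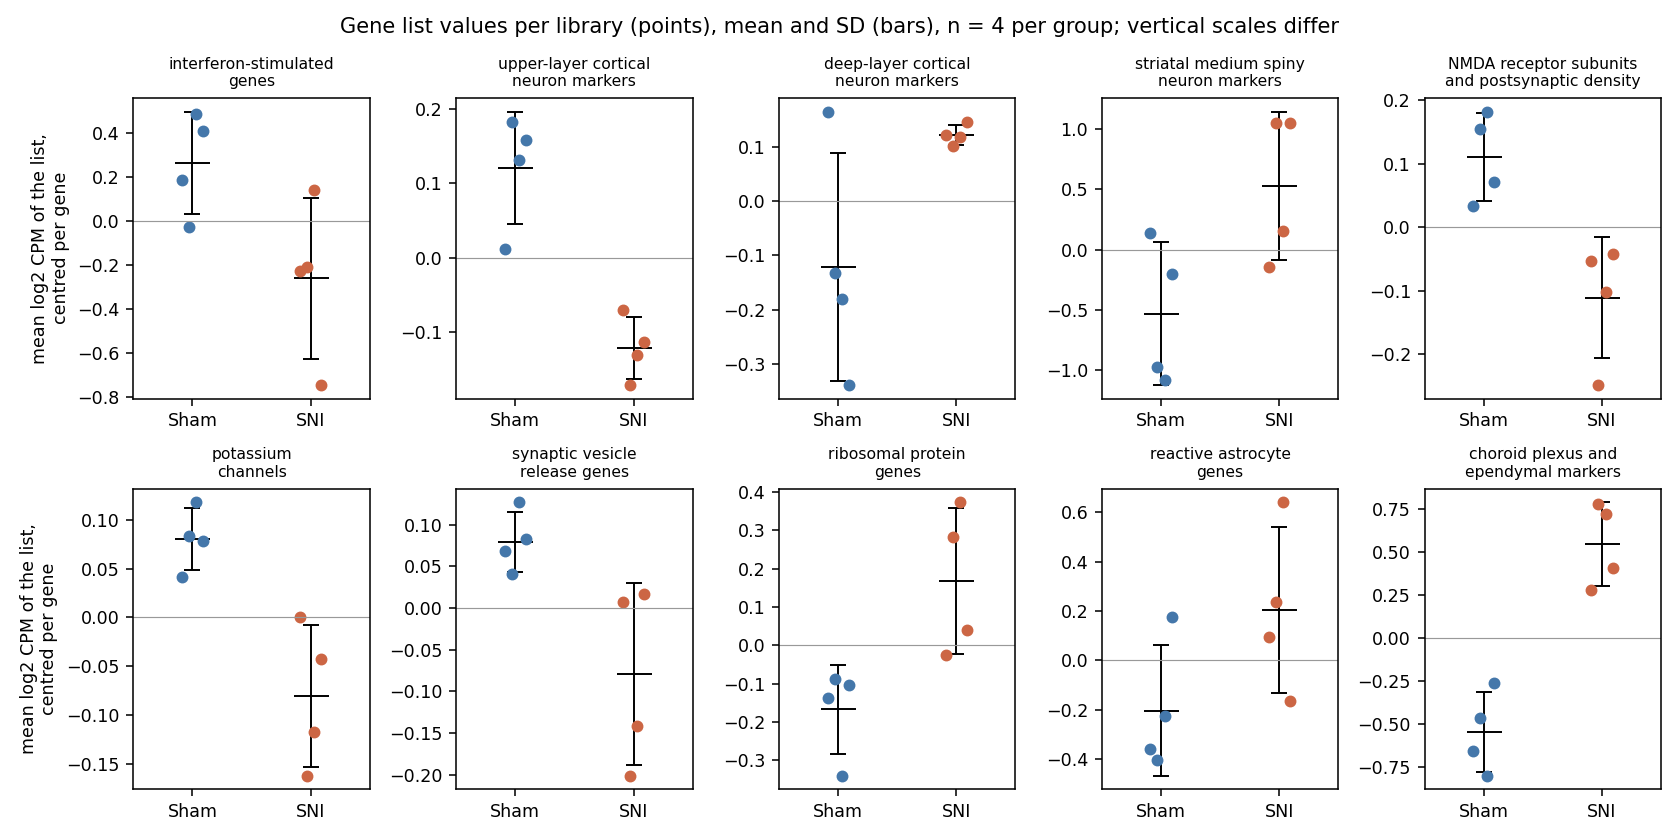
Mean centred log2 CPM of 10 gene lists (vertical axis, scale differing by panel) in each library, as points, for Sham and SNI; black bars show the mean and SD of 4 libraries. Upper-layer values separated the groups (0.12 ± 0.076 in sham, -0.12 ± 0.042 in SNI, SD, n = 4 libraries). Interferon, deep-layer, striatal and reactive astrocyte values overlapped between the groups.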

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

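A sample that stood far from the other 3 of its group was looked for in 201 reported items (402 groups), and 18 groups held one, against about 20 expected by chance. The score in each case is the gap to the nearest sample as a share of the group's range, compared with Dixon's 95% critical value. No explanation was tested for these samples.

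In the sham group, replicate 2 was apart for C1s1 (0.838, highest at 0.730 CPM against at most 0.442), Ankub1 (0.961, lowest at 0.332 CPM), Mdga1 (0.834, highest at 31.5 CPM against at most 19.5) and Dbp (0.956, lowest at 40.6 CPM). Replicate 3 was highest for Erbb4 (0.846) and for the hypoxia and glycolysis list (0.897). Replicate 4 was highest for Vtn (0.834) and lowest for Vgf (0.884, 362 CPM against at least 438). Replicate 1 was lowest for the GABA receptor list (0.968).

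In the SNI group, replicate 1 was highest for Ntsr1 (0.888), Eomes (0.839) and Grin2b (0.954, 325 CPM against at most 260). Replicate 2 was highest for Grin2a (0.847, 154 CPM against at most 130) and Nr3c2 (0.832). Replicate 3 was highest for Aebp1 (0.915), Atf4 (0.8291) and the TNF receptor signalling list (0.848, value 0.17 against at most 0.012), and lowest for Adcyap1 (0.911).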

How the results depend on the processing

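Alternatives chosen after seeing the data were the GC offsets, the striatal covariate and leaving out SNI replicates 2 and 4 or 2 and 3. All 698 called genes kept their direction under each scaling, filter, tool, block and leave-one-out fit that tested them. With a replicate block 518 genes passed (212 higher, 306 lower), 119 list members and 20 lists. Same-numbered libraries did not deviate together (correlations -0.035, -0.0056, -0.082 and -0.15), and no sham library correlated best with its own number, so the numbers are not taken as pairs.

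DESeq2 called 1153 genes (503 higher, 650 lower) and 234 list members. Leaving out 1 library gave 258 to 858 genes (90 to 405 higher, 168 to 453 lower), 56 to 188 list members, 19 to 25 lists, and 4 to 10 lists with an unadjusted exact p under 0.05 against 9 (0 when adjusted). An FDR of 0.1 gave 1279 genes (591 higher, 688 lower). An unadjusted p under 0.05 with a log2 change of 1 gave 204 (140 and 64), and FDR 0.05 with that change 99 (61 and 38), by construction. Without SNI replicates 2 and 4, 438 genes (173 and 265) and 89 list members passed, with fewer libraries. Without SNI replicates 2 and 3, 178 genes (50 and 128) and 49 list members passed, 159 of the 178 shared with the 698. The striatal covariate left 7 genes (2 and 5) and 3 list members, and 697 to 698 of the called genes kept their direction in these last alternatives. The covariate takes up variance shared with the group and a residual degree of freedom.

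camera with an estimated correlation called 0 lists, fry 6 in its directional form and 35 in its mixed form, against 20. Medians or tests turned for the microglia list with ranks (median 0.32, now called higher). With the covariate they turned for oligodendrocyte genes (-0.35) and respiratory chain genes (-0.0746), and without SNI replicates 2 and 3 for endothelial markers (-0.138). The cause of these turns was not tested. Striatal markers also turned with the covariate (-0.053). As the covariate is that list's own value per library, its group difference was removed by construction. Depth limits genes near 1 CPM: most of the largest rises sit there.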

Other observations

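Tests chosen only after the result was seen are those of the cilium genes, of microglial number, of the chromosome 9 stretch and of the allele for Cx3cr1, of neuron share for the layer markers, of immune cell number for the interferon genes, and the fits with GC offsets, with the striatal covariate, without SNI replicates 2 and 4, and without SNI replicates 2 and 3.

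Of 64 tested genes of the ciliary axoneme, a group chosen after seeing Dnah6 and Cfap126, 9 rose and 0 fell at the FDR threshold, 47 had a positive fold change, and the median log2 fold change was 0.36, or 0.36 without Dnah6. The values per library separated the groups (exact two-sided permutation p = 0.0286). The unadjusted p was 6.2e-09 by camera and 0.024 with an estimated correlation. Cfap54 and Cfap44 had 0.84 and 1.23, and Tppp3 0.57. As the group was picked from these data, these p-values are not independent evidence, and a rise of the group is a hypothesis. Without Dnah6 and the 3 genes shared with the choroid plexus and ependymal list, 7 of 60 rose, 43 had a positive fold change and the median was 0.34. That list, which holds genes of ciliated cells, moved with it: 4 of 8 rose, 7 adjusted over the list alone, with a median of 1.22. Its values were -0.55 ± 0.23 in sham and 0.55 ± 0.24 in SNI (SD, n = 4 libraries each), so a different share of ependymal tissue was not separated from a change in cilium genes.

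Several lists gave little. Of 12 olfactory bulb and neuroblast markers 0 passed, with 1 higher adjusted over the list alone, and 10 had a negative fold change. Sham replicate 2 was highest on this list, at 1.66 against -0.976 to 0.388 in the other sham libraries. Without it the log2 fold change of Th went from -2.2 to -1.18 and that of Eomes from -3.02 to -1.73. Of 18 endothelial markers 0 passed, of 12 pericyte 0, of 17 meningeal 0 and of 81 nuclear-encoded respiratory chain genes 0. Of 22 cholesterol synthesis genes 0 passed, with 3 higher adjusted over the list alone. Of 14 oligodendrocyte precursor markers 2 fell, Gpr17 and Tnr. Of 13 mitochondrially encoded transcripts mt-Nd3 rose, of 30 hypoxia and glycolysis genes Slc16a7 and Eno1 fell, and of 27 heat shock genes Calr fell. These calls ended when single libraries were left out, that of mt-Nd3 in 7 of 8 (highest edgeR adjusted p = 0.15), those of Slc16a7, Eno1 and Calr in 6 of 8 (0.145, 0.116 and 0.125), and those of Gpr17 and Tnr in 3 of 8 (0.0666 and 0.0938). Of 7 red blood cell transcripts Hba-a1 rose and Hba-a2 fell, the near-identical copies whose reads were divided uncertainly. In all, 5 of the 7 had a positive and 2 a negative fold change, with a median of 0.86 (camera adjusted p = 0.21). Hbb-bt, Alas2 and Hbb-bs had 1.26, 0.93 and 0.86 and did not pass. Y-linked genes were counted in all 8 libraries.

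The 698 gene calls were set against other groupings of the libraries. Of the 35 splits into 4 and 4, 1 called as many, the real one. The highest of the others called 1 gene, which argues against chance as the source of the count. Chance is not excluded, as 1 of 35 is the smallest share that this test can give. The other splits mix the groups, so any group difference adds to their spread and lowers their calls. What made the groups differ is not addressed by this test. For the lists chance is not argued against: 12 of 35 splits gave at least 20 lists, and the highest of the others gave 29. The camera calls at the preset correlation therefore do not show that a list differed by group.

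The first pattern is the loss of Cx3cr1. Fewer microglia would lower the other markers alike, but the median of the 17 others was 0.33 and 15 of them were higher in SNI. The lowest was Fcrls at -1.19. A stretch of chromosome 9 from another strain around the gene would make nearby calls more frequent, but 5 of 112 genes within 10 Mb were called against 684 of 13704 elsewhere (odds ratio 0.889, 95% interval 0.282 to 2.15, Fisher's exact p = 1), which leaves this open. A different Cx3cr1 allele in the SNI mice may account for it, but only if it removed nearly all of the transcript. Every SNI library held 3.00% to 4.36% of the sham mean (mean 3.76%). That prediction was written after these values were seen, and nothing in the counts follows from the injury that would separate it from an allele. The injury and an allele cannot be told apart here, since the genotype labels read the same in both groups and no read sequence was used. The chromosome 9 stretch stays open beside them.

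The second pattern is the fall of upper-layer markers, 3 called genes with a mean log2 fold change of -0.68. A lower share of neurons would lower both layers, but deep-layer minus upper-layer values rose by 0.49 in SNI (exact p = 0.0286). That argues against an equal fall of both layers as the whole cause. The test was chosen after both lists had been seen to move apart, so its outcome was largely set. A lower neuron share beside another change stays open, as 10 of 12 excitatory neuron markers had a negative fold change. GC content is argued against, as the mean stayed at -0.65 with 3 calls after correction. More striatum in SNI dissections may contribute: with the striatal covariate the mean was -0.59 and 0 calls remained. That fit called 7 genes in all, so the lost calls are not particular to these markers. Lamp5 then had -0.84 ± 0.16 (before, -0.80 ± 0.108), Mdga1 -0.76 ± 0.272 (-0.84 ± 0.177) and Cux2 -0.17 ± 0.121 (-0.40 ± 0.1, all SE), so the calls of Lamp5 and Mdga1 ended through wider errors and that of Cux2 through a smaller change. Without SNI replicates 2 and 4, which had the highest striatal values, Lamp5 stayed called (-0.85, edgeR adjusted p = 0.0118). Mdga1 (-0.93, 0.0657) and Cux2 (-0.25, 0.204) did not. The fall of Lamp5 thus did not rest on those 2 libraries, and for Cux2 the account stays open. Both fits address striatal tissue only. Other differences in the tissue taken, such as the share of each cortical layer, were not tested for any of the 3 genes.

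The third pattern is the fall of interferon-stimulated genes, 10 called with a median of -0.78. Fewer microglia or immune cells are argued against, as the medians of the other microglia markers and the peripheral immune list were 0.33 and 1.39. For immune cells this is weak, as 0 of the 8 markers passed and the list's values overlapped between the groups. Within SNI the interferon and immune lists were both lowest in replicate 4 (-0.747 and -0.47) and highest in replicate 3 (0.14 and 1.63). GC content is argued against, as the median stayed at -0.78 with 10 calls. Without SNI replicate 4 the median was -0.66 and 7 stayed called, so those 7 calls did not rest on that library alone. The 10 genes were chosen as called with all libraries, so this fit does not speak for the whole list. Over the whole list the groups overlapped, with SNI replicate 3 (0.14) above Sham replicate 2 (-0.031). An effect of the injury remains open and untested. With the striatal covariate 0 of the 10 stayed called, with a median of -0.62. That fit called 7 genes in all, 6 of them among the 698, so the lost calls are not particular to interferon-stimulated genes.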
